A study of Mus musculus with 2 samples.

How the data were processed

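Total RNA from whole mouse hearts was measured on 1-colour Agilent whole mouse genome arrays in 2 samples, 1 sham-operated and 1 infarcted, both 3 days after surgery; groups were taken from the treatment label of each sample. Per the file headers, the arrays were scanned and their spots quantified with Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1. Per the file headers, the deposited processed intensity of each spot was background-subtracted and detrended but not scaled between arrays, and the probes' coordinates are on mm9. The deposited mean and local background intensities and the 0 or 1 spot flags come from the same software, per the file headers. The authors' table of processed values holds 1 linear intensity for each of 39429 probes. Its columns share 99.6% of their sorted values, lie within 0.728% of the mean of the sorted scanner signals and both have a median of 95.1, so quantile normalization was read from the values and is not stated in the sources used here.

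The main value was log2 of the processed intensity minus the array's 75th percentile of it over non-control spots, which removed a difference of 0.32 between the arrays. Spots with an outlier flag were left out, 165 on the sham array and 211 on the infarcted array, and the spots of a probe were averaged. A probe was detected on an array if more of its spots than not were well above background. A gene took the value of its probe with the highest mean over both arrays. Genes detected on 1 array only, 674 in the infarcted and 651 in the sham heart, were given a bound: the bright value against the higher of the lowest signal among probes well above background on the other array and the probe's own value. The lowest such signals were 20.6 on the sham array and 24.8 on the infarcted array. The number of arrays limits the precision.

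Of the probes, 26761 were named through the accession in the scanner files, using RefSeq names of the GRCm38.p6 assembly for names only, 3814 through their symbol and 639 through a synonym; 2044 kept the name in the file and 6171 were unnamed. Members of families with near-identical sequences, such as the globin, stefin, guanylate-binding protein and olfactory receptor genes, can share hybridisation, so values of single members are uncertain.

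No test across samples was possible with 1 array per group, so no p-value is given. Genes were counted at 2-fold and 4-fold. Before the data were examined, 50 gene lists were fixed, 26 of pathways and 24 of cell types, and each list's median difference was set against 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. After the data were seen, 3 lists were added. They hold clock output genes, clock genes of opposite phase and interferon-gamma inducible GTPases, and were made because Dbp, Ciart, Igtp and Gbp6 stood near the end of the ranking.

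Genes were named by a rule fixed beforehand: the 12 with the most positive and the 12 with the most negative difference among genes detected on both arrays whose detected probes share a direction; the 4 largest bounds each way; up to 4 members with the largest difference in each list in its main direction and 2 in the other; a fixed set of cardiac, matrix and chromosome genes; and common reference genes. Genes with clone names were left out of the first parts.

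Technical spread was taken from repeated spots, from the scanner's signal error and from different probes of a gene. The counts, list medians and named genes were recomputed under 10 alternatives, 1 of which, scaling to spike-in controls, was chosen after the data were seen. The planned ones were scaling to the array median, quantile normalization, the 75th percentile over spots detected on both arrays, normexp background correction with an offset of 50, the authors' processed values, no filter on dim probes, genes detected on both arrays only, the mean over probes, and outlier spots kept. After the data were seen, each list was also set against random lists matched within each alternative. A list median was called moved when it changed by more than 0.16, the median SD between probes of a gene.

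The steps were tested on simulated data made from the sham array with an SD of 0.07 per spot and 16480 genes: of 150 genes changed by 1.5 to 3 on the log2 scale 144 passed the 2-fold rule, none of 50 changed by 0.5 did, and none of 16280 unchanged genes did. Of 200 random unchanged lists of 20 genes, 5.0% lay outside the central 95% of matched lists. The simulated noise came from repeated spots of detected probes and was smaller than the spread between probes of a gene. Both simulated arrays carried the sham array's detection flags, apart from genes lowered below the floor. The simulation therefore checks the steps and does not estimate how many unchanged genes pass the 2-fold rule between real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for normexp, were used.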

Results

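Gene expression was measured in whole hearts of male C57BL/6 mice, an inbred laboratory strain, at 8 weeks of age and 3 days after surgery. 1 sample was of sham-operated heart, and 1 was of heart whose left anterior descending coronary artery, which supplies much of the left ventricle, had been closed for good so that an infarct formed. Total RNA from each was labelled with Cy3 and hybridised to 1 array of 39429 different 60-base probes. On the sham array 64.6% of 43020 spots were well above background and on the infarcted array 64.8%, and no spot was saturated. The arrays held probes for 24164 named genes, of which 17142 were measured, 15817 of them on both arrays. Because there were no replicates, the spread between animals, dissections, labellings and hybridisations is unknown, and array position cannot be told apart from group. The labels do not say whether a sample was 1 heart or a pool. All values therefore compare these 2 samples, and differences are described as higher or lower by a fixed rule of size, without a test across animals.

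The comparison asked how gene expression in the heart differed 3 days after infarction. In the infarcted heart, genes of cell division, extracellular matrix, matrix remodelling and myeloid cells were higher, and genes of cardiomyocyte ion handling, fatty acid oxidation, the tricarboxylic acid cycle and amino acid catabolism were lower. At least a 2-fold difference was found for 1381 higher and 974 lower genes, which were 8.06% and 5.68% of the genes measured. A 4-fold difference was reached by 338 higher and 162 lower genes. The median difference over all genes was -0.11 on the log2 scale, and the arrays correlated at r = 0.97 across genes, which are not independent replicates. The counts depended on how dim spots were treated: with normexp background correction they were 840 higher and 582 lower at 2-fold and 101 and 53 at 4-fold. Without a filter on dim probes 1702 genes were at least 2-fold lower, and 558 were higher and 381 lower at 4-fold, whereas 62 were at least 4-fold lower among genes detected on both arrays.

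Measurement error within the arrays was, at its median, well under a 2-fold difference. The SD of a single-spot difference had a median of 0.09 on the log2 scale over 284 probes spotted repeatedly and detected on both arrays. Its 90th percentile was 0.27, and dimmer spots are not covered by it. The scanner's own error of a difference had a median of 0.20. Different probes of the same gene differed with a median SD of 0.16 over 4419 genes, with a 90th percentile of 0.51 and a root mean square of 0.35. Among the 678 of those genes with a probe at least 2-fold different, 94 had another probe pointing the opposite way. Of the 500 genes at least 4-fold different, 194 were well above background on 1 array only, so their values are bounds, each resting on 1 spot per array.

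**Figure D1:**
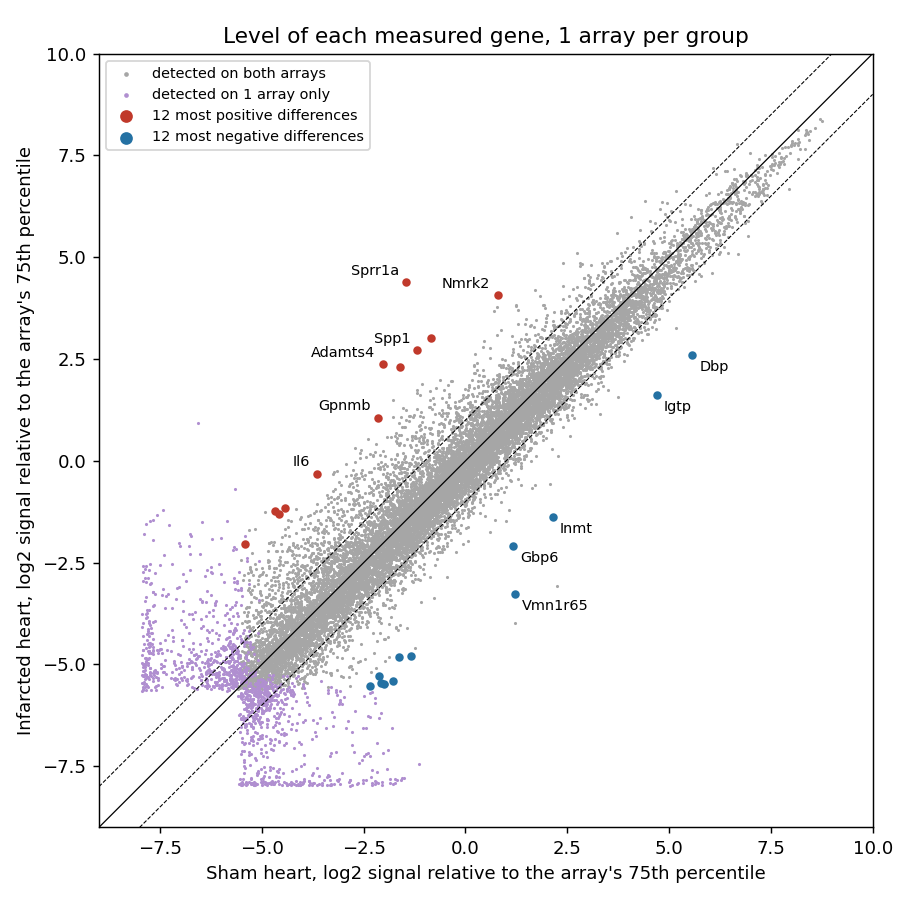
Level of each measured gene in the infarcted heart against the sham heart, both as log2 signal relative to the array's 75th percentile, with 1 array per group; grey points are genes detected on both arrays, purple points genes detected on 1 array, drawn at their own signal and not at their bound, and red and blue points the 12 most positive and 12 most negative genes after clone names and genes whose probes point opposite ways are left out. The solid line marks equal levels and the dashed lines a 2-fold difference, beyond which lie 1167 grey or red points above and 748 grey or blue points below, and Sprr1a stands 57.4-fold above the line of equality.

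Among genes detected on both arrays, with clone names and genes whose probes point opposite ways left out, the most positive differences began with Sprr1a, a small proline-rich protein known from stressed cardiomyocytes and epithelia, which was 57.4-fold higher in the infarcted heart (probe at chromosome 3, 92287955 to 92288014 in mm9). The matrix protease gene Adamts4 was 21.3-fold higher (chromosome 1, 173190709 to 173190768), and its probes gave log2 differences from 3.64 to 4.41. Spp1, which encodes osteopontin, was 15.0-fold higher and the membrane protease gene Adam8 14.6-fold. The log2 difference of the cytokine gene Il6 was 3.32. Nmrk2, a nicotinamide riboside kinase of muscle, was 9.66-fold higher (chromosome 10, 80662033 to 80662092), and Gpnmb, a glycoprotein of phagocytes, 9.25-fold. Acod1, which makes itaconate in activated macrophages, was 9.66-fold higher over repeated spots. Tnnt3, the fast skeletal troponin T gene, was 9.57-fold higher, Inava 11.0-fold and the chemokine receptor gene Cxcr5 10.3-fold, all from dim signals in the sham heart. With normexp the log2 difference of Cxcr5 was 1.61 in place of 3.37, of Inava 2.13 in place of 3.46, of Il6 2.42 in place of 3.32, of Acod1 2.01 in place of 3.27 and of Tnnt3 1.995 in place of 3.26, while that of Sprr1a was 5.54 in place of 5.84. Over all named genes, it moved 98 of 267 by more than the spread between probes and their scanner error.

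At the other end, Dbp, a transcription factor gene of the circadian clock's output, was 7.83-fold lower in the infarcted heart (chromosome 7, 52965461 to 52965520), and its 2 probes gave log2 differences of -2.97 and -2.79. The interferon-inducible GTPase gene Igtp was 8.43-fold lower over 10 spots per array (chromosome 11, 58020927 to 58020986), and the 2 probes of its relative Gbp6 gave log2 differences of -3.25 and -1.91. Inmt, which encodes indolethylamine N-methyltransferase, was 11.5-fold lower (chromosome 6, 55120770 to 55120829). The vomeronasal receptor gene Vmn1r65 was 22.3-fold lower, Cyp2d26 12.5-fold, Aknad1 11.0-fold, Zfp456 10.9-fold, Atp12a 10.5-fold, Obi1 9.19-fold and Kcna3 8.97-fold, and Lactbl1 had a log2 difference of -3.17. Each value of those 8 genes rests on 1 spot per array, and all but Vmn1r65 were dim in the infarcted heart. With normexp the log2 difference of Vmn1r65 was -3.96 and those of the others lay between -2.25 for Zfp456 and -1.82 for Lactbl1. The second probe of Aknad1 gave -0.45 against -3.46 on the log2 scale. No exon or untranslated-region annotation of mm9 was used here.

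Genes well above background on 1 array have a bound in place of a fold. Among genes detected in the infarcted heart alone, Crct1, a gene of the cornified envelope, was at least 92.0-fold higher by 1 of its 2 probes, the other being detected on neither array, Tnc, which encodes the matrix protein tenascin C, at least 30.2-fold, Olfr71 at least 20.9-fold and Smim6 at least 17.5-fold. In the opposite direction Olfr1352 was at least 22.8-fold lower, D7Ertd807e at least 17.7-fold, Pramel at least 16.9-fold and Olfr195 at least 15.8-fold. With normexp the bounds were smaller, on the log2 scale 4.43 for Crct1 in place of 6.52 and 2.48 for Tnc in place of 4.92. Those of Olfr71 and Smim6 were 2.56 and 2.17, and the 4 lower genes lay between -2.89 for Olfr1352 and -2.43 for Olfr195. The second probe of Tnc gave a bound of 3.71. Olfactory and vomeronasal receptor genes, which are rarely used outside sensory tissue, had 10 members at least 4-fold higher and 20 lower among 209 measured of 1364 on the array, 115 of them detected on 1 array only. That is 14.4% of the 209, against 9.40% from other genes of like level and detection.

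Gene lists fixed before the data were examined were each compared with 10000 random lists matched on level. Of 50 lists, 19 had a median above the central 95% of matched lists, 10 had a median below it and 21 lay within it. Several lists share members, such as Myh6 in the cardiomyocyte, ventricular and sarcomere lists, so these are not counts of independent lists. Of the 29 outside it, 24 stayed on the same side under each of the 10 alternatives.

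**Figure D2:**
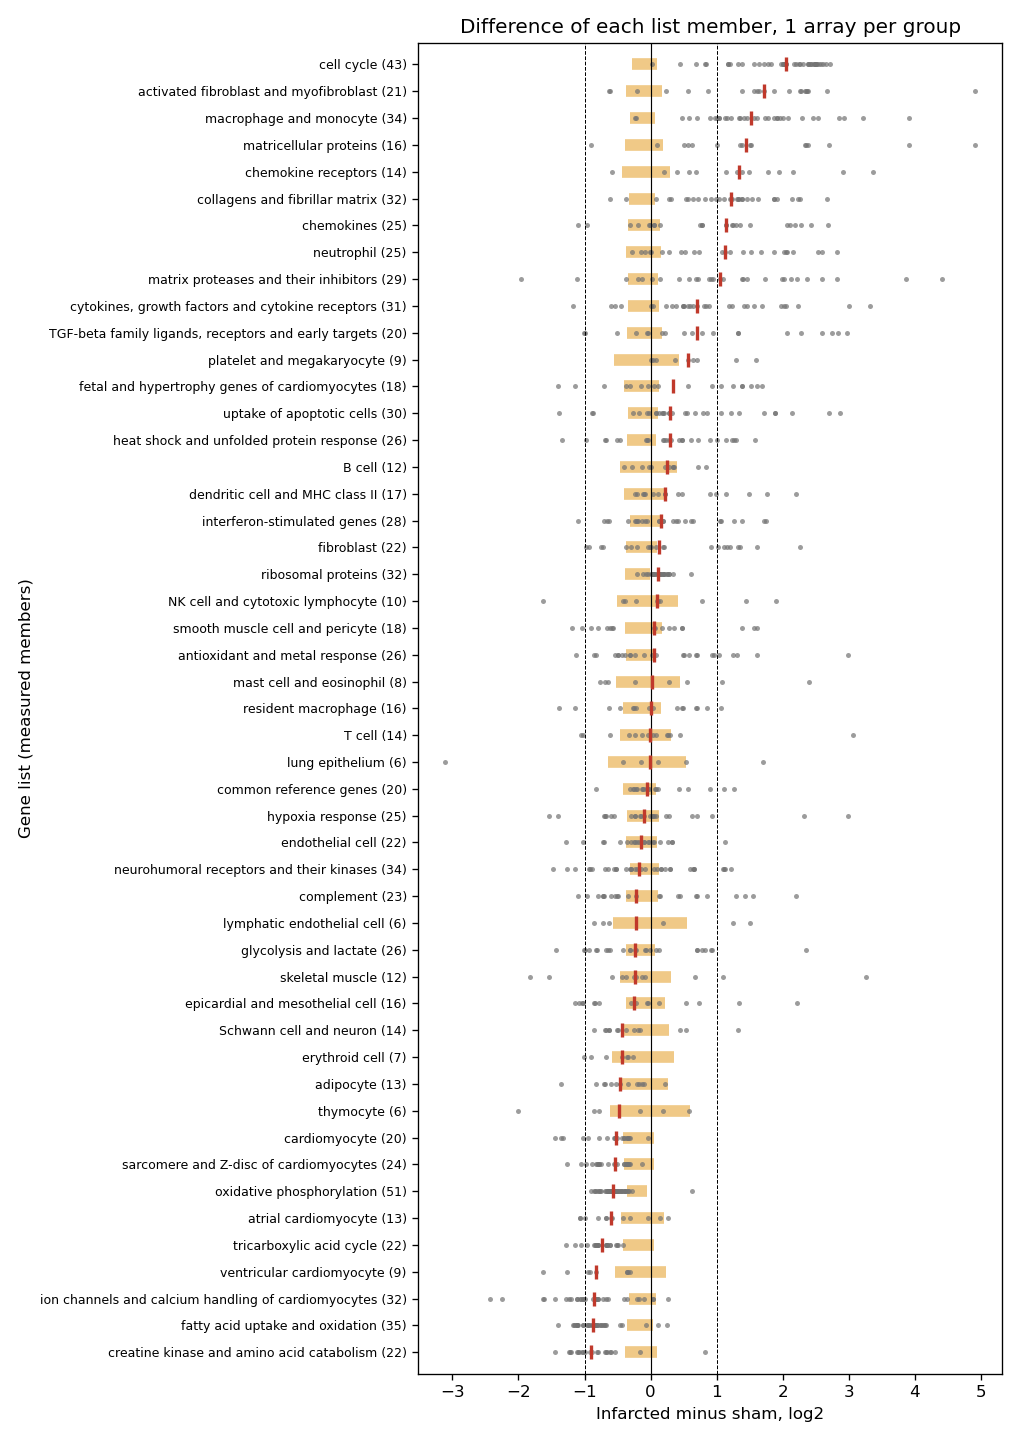
Infarcted minus sham log2 difference of each measured member (grey points) of the fixed gene lists, with the list median (red bar) and the central 95% of medians of 10000 level-matched random lists (orange band), from 1 array per group. Cell cycle genes have the most positive median, 2.05, and creatine kinase and amino acid catabolism genes the most negative, -0.90; the list of chromosome genes is not drawn.

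Of the 50 lists, the cell cycle list had the highest median: 38 of 43 were at least 2-fold higher, all 43 were above 0, and the median was 2.05 on the log2 scale against a matched range of -0.27 to 0.10. The mitotic checkpoint kinase gene Bub1 was 6.55-fold higher, the centromere motor gene Cenpe 6.32-fold, the mitotic kinase gene Plk1 6.09-fold and the spindle gene Prc1 5.97-fold.

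Collagens and fibrillar matrix genes were higher as a group, with 20 of 32 at least 2-fold higher, none at least 2-fold lower and a median of 1.22 (matched range -0.33 to 0.07). Col8a1 was 6.33-fold higher, the collagen cross-linking enzyme genes Lox and Loxl3 4.81-fold and 4.68-fold, and Col18a1 4.42-fold. Col1a1 and Col3a1, the main fibrillar collagens of scar, were 2.29-fold and 1.89-fold higher. Matricellular proteins, which bind matrix and signal to cells, had 11 of 16 members at least 2-fold higher and a median of 1.45 (matched range -0.39 to 0.19). Besides Tnc and Spp1, Thbs1 was 6.50-fold higher, Ccn4 5.24-fold and Postn, which encodes periostin, 5.05-fold. Matrix proteases and their inhibitors had 15 of 29 members at least 2-fold higher and 2 lower, with a median of 1.05 (matched range -0.34 to 0.12). The neutrophil collagenase gene Mmp8 was at least 7.06-fold higher. The inhibitor genes Timp4 and Timp3 were 3.88-fold and 2.17-fold lower. In the TGF-beta family, 8 of 20 genes were at least 2-fold higher and 1, Tgfbr3, was lower at 2.02-fold, with a median of 0.70 (matched range -0.35 to 0.18). Of the listed genes, Ltbp2 was 7.85-fold higher, the activin subunit gene Inhba 7.12-fold and the stress-induced ligand gene Gdf15 6.72-fold.

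Markers of activated fibroblasts and myofibroblasts were higher in 15 of 21 cases at 2-fold, with a median of 1.72 (matched range -0.37 to 0.17), and included Timp1 at 5.15-fold. General fibroblast markers had a median of 0.13 (matched range -0.38 to 0.10): 8 of 22 were at least 2-fold higher, and the median of 0.063 with normexp lay within its matched range; those higher included Thy1 at 3.05-fold, Mfap5 at 2.55-fold and Fbln2 at 2.51-fold, and 9 lay below 0. The contractile genes Acta2, Tagln and Cnn1, which smooth muscle and myofibroblasts share, were 2.61-fold, 2.95-fold and 3.04-fold higher. The whole smooth muscle and pericyte list lay within its matched range, with a median of 0.06, 3 of 18 members at least 2-fold higher and 2 lower (Abcc9 2.28-fold and Colec11 2.06-fold).

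Macrophage and monocyte markers were at least 2-fold higher for 27 of 34 genes, with a median of 1.52 (matched range -0.32 to 0.07). Chil3, a chitinase-like protein gene of activated macrophages, was 7.61-fold higher and the C-type lectin gene Clec4d 7.24-fold. For resident macrophage markers the median was 0.01, or -0.0015 with normexp, inside the matched range of -0.41 to 0.15, with Timd4 2.61-fold and Cd163 2.21-fold lower and Stab1 2.10-fold higher. Neutrophil markers had a median of 1.12 (matched range -0.37 to 0.16) and 14 of 25 at least 2-fold higher, while 4 lay below 0 and 3 were known only as bounds. Those higher included Slfn4 at 6.02-fold, Clec4e at 5.79-fold and Cxcr2 at 4.45-fold. Clec4e is also on the macrophage and monocyte list, so the lists are not separate evidence. Many neutrophil values came from dim signals, and the median of the neutrophil list was 0.45 with normexp. Dendritic cell and MHC class II genes had a median of 0.22 (matched range -0.41 to 0.20), with Itgax 4.59-fold and Fscn1 3.38-fold higher among 4 of 17 at 2-fold. Platelet and megakaryocyte genes had a median of 0.56 (matched range -0.56 to 0.43), with Ppbp 3.01-fold and Pf4 2.46-fold higher, and the median was 0.17 with normexp and 0.37, within its matched range, as a mean over probes. Erythroid genes were inside their matched range at -0.44, with 0 of 7 at least 2-fold higher and Slc4a1 2.01-fold lower.

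Lymphocyte lists lay within their matched ranges. The T cell median was -0.0027, or 0.035 with array median scaling, with Cd3d and Cd28 2.09-fold and 2.02-fold lower and Il7r, also found on other leukocytes, at least 8.34-fold higher. B cell genes had a median of 0.25 with none at 2-fold, and the median was -0.11 with normexp. NK cell genes had a median of 0.10, with Eomes at least 3.73-fold higher and Klra8 3.08-fold lower, and the median was -0.16 with normexp. The mast cell and eosinophil median was 0.02, with Siglecf at least 5.29-fold and Kit 2.12-fold higher, and -0.24 over genes detected on both arrays.

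Chemokine genes, which attract leukocytes, were at least 2-fold higher for 13 of 25 members, with a median of 1.14 (matched range -0.35 to 0.15), which was 0.76 with normexp, beside a macrophage and monocyte median of 1.52. Ccl4 was 6.42-fold higher, Ccl2 5.37-fold over 10 spots per array, Ccl3 4.85-fold and Ccl7 4.53-fold, whereas the eotaxin gene Ccl11 was 2.15-fold lower. Chemokine receptors had 9 of 14 members at least 2-fold higher and a median of 1.34 (matched range -0.43 to 0.30), which was 0.75 with normexp. Cxcr6 was 7.54-fold and Cx3cr1 3.83-fold higher. Cytokines, growth factors and their receptors had a median of 0.71 (matched range -0.34 to 0.13) and 12 of 31 at least 2-fold higher, including Il11 at 4.67-fold, the decoy receptor gene Il1r2 at 4.15-fold and the growth factor gene Ereg at a minimum of 7.98-fold, with Il15 2.25-fold lower.

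Genes for the uptake of apoptotic cells had 9 of 30 members at least 2-fold higher and 1 lower, with a median of 0.30 (matched range -0.34 to 0.11). The phosphatidylserine receptor gene Cd300lf was 7.31-fold higher, although its 3 probes ranged from 0.75 to 2.87 on the log2 scale. The pentraxin gene Ptx3 was 4.43-fold and the engulfment receptor gene Megf10 3.68-fold higher. Mfge8, which bridges apoptotic cells to phagocytes, was 1.14-fold higher. Interferon-stimulated genes had 6 of 28 members at least 2-fold higher, among them Mx1 at 3.36-fold and Oas3 at 3.29-fold. In the other direction 1 was at least 2-fold lower, and 12 of the 28 lay below 0. The median of the interferon-stimulated genes was 0.16 (matched range -0.32 to 0.14). Their median lay within its matched range with normexp, at 0.080, after quantile normalization, at 0.16, and in the authors' processed values, at 0.18. Complement genes lay within their matched range at -0.22 and above it, at 0.13, as a mean over probes; the anaphylatoxin receptor genes C5ar1 and C3ar1 were 4.59-fold and 2.93-fold higher and C7 2.14-fold lower.

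Cardiomyocyte markers were lower, all 20 of them below 0, with a median of -0.53 (matched range -0.42 to 0.05) and 4 at least 2-fold lower. The calcium pump regulator gene Pln was 2.74-fold lower, Cmya5 2.56-fold, the natriuretic peptide convertase gene Corin 2.51-fold and the calcium release channel gene Ryr2 2.03-fold. Many of these probes are among the brightest, and the median was -0.30 after quantile normalization and -0.25 in the authors' processed values, where it lay within its matched range. Sarcomere and Z-disc genes had a median of -0.54 (matched range -0.40 to 0.05), with 2 of 24 at least 2-fold lower, Tcap at 2.40-fold and Myot at 2.07-fold. Atrial markers had a median of -0.59 (matched range -0.45 to 0.20), with Stard10 and Kcnj3 at least 2-fold lower. Ventricular markers had a median of -0.83 (matched range -0.54 to 0.24), or -0.60 without the 1 gene known only as a bound, with Kcnip2 3.08-fold lower.

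Ion channel and calcium-handling genes were lower in 29 of 32 cases, 14 of them at least 2-fold, with a median of -0.86 (matched range -0.33 to 0.09). The potassium channel subunit gene Kcnv2 was 5.38-fold lower and the sodium channel subunit gene Scn4b 3.06-fold. Fetal and hypertrophy genes moved apart, with 7 of 18 at least 2-fold higher, 2 lower and a median of 0.34 (matched range -0.40 to 0.13). Actn1 was 3.23-fold, Rcan1, a calcineurin regulator, 2.87-fold and Ccn2 2.61-fold higher. The natriuretic peptide gene Nppb was 2.60-fold higher, while the log2 difference of Nppa was -0.05, or 0.22 after quantile normalization and 0.30 in the authors' processed values. The slow myosin gene Myh7 was 2.65-fold and Hopx 2.22-fold lower, and the probes of the main adult myosin gene Myh6 gave -1.01 and -0.34. The Myh7 value rests on 1 bright probe, at a sham level of 6.93 on the log2 scale. Whether that probe shares hybridisation with Myh6 was not tested, so a fall of Myh7 itself is uncertain. Neurohumoral receptors lay within their matched range at -0.17, with the purinergic receptor gene P2ry6 2.32-fold and the receptor kinase gene Grk5 2.15-fold higher and the adrenergic receptor gene Adra1a 2.79-fold lower.

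Genes of fatty acid oxidation, the tricarboxylic acid cycle, oxidative phosphorylation and amino acid catabolism were lower, beside a cardiomyocyte marker median of -0.53. Fatty acid uptake and oxidation genes had a median of -0.86 (matched range -0.35 to 0.03), 33 of 35 below 0 and 10 at least 2-fold lower, among them the transcriptional regulators Ppargc1a at 2.27-fold and Ppara at 2.23-fold, and Eci1 at 2.22-fold. The tricarboxylic acid cycle median was -0.74 (matched range -0.41 to 0.05), with 3 of 22 genes at least 2-fold lower, Suclg2 at 2.43-fold. Oxidative phosphorylation genes had a median of -0.57 (matched range -0.35 to -0.06), with 50 of 51 below 0 and 0 at 2-fold. Creatine kinase and amino acid catabolism genes had a median of -0.90 (matched range -0.38 to 0.09) and 9 of 22 at least 2-fold lower, including Aldh6a1 at 2.72-fold and the muscle creatine kinase gene Ckm at 2.32-fold. Glycolysis genes lay within their matched range at -0.23, or -0.038 after quantile normalization, with the lactate exporter gene Slc16a3 5.11-fold higher and Pfkfb2 2.71-fold lower.

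Hypoxia response genes had a median of -0.09, within the matched range, with the haem-degrading enzyme gene Hmox1 7.95-fold and the carbonic anhydrase gene Car9 5.01-fold higher and the oxygen sensor gene Egln1 2.90-fold lower. Heat shock and unfolded protein response genes had a median of 0.29 (matched range -0.35 to 0.08) and 6 of 26 at least 2-fold higher, Asns at 2.99-fold, with Herpud1 2.52-fold lower. Antioxidant genes were within their matched range at 0.05; apart from Hmox1, the phagocyte oxidase subunit gene Ncf4 was 3.04-fold higher, and Txnip was 2.19-fold lower. Ribosomal protein genes had a median of 0.12, above the matched range of -0.39 to -0.0041 although none reached 2-fold, and 0.29 after quantile normalization.

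The lists of other cell types lay within their matched ranges, apart from the adipocyte list. The endothelial median was -0.14, within the matched range, with Rgcc 2.43-fold and Aqp1 2.04-fold lower and Cldn5 2.18-fold higher. Lymphatic endothelial genes had a median of -0.22 over 6 genes, or -0.62, below its matched range, without a filter on dim probes, with Nts 2.84-fold and Pdpn 2.36-fold higher. Epicardial and mesothelial genes had a median of -0.26, with Muc16 2.20-fold lower and Saa3 4.64-fold higher. Adipocyte genes had a median of -0.47, just below the matched range of -0.46 to 0.26, with Dgat2 2.56-fold lower, and lay within its range at -0.28 without a filter on dim probes and at -0.39 with normexp. The Schwann cell and neuron median was -0.43, at the lower edge of its matched range, and lay below it under 7 of the 10 alternatives. For tissues next to the heart, the skeletal muscle median was -0.24, the lung epithelium median -0.01, or 0.028 with array median scaling, and the thymocyte median -0.47, or -0.16 without the filter, all within their matched ranges.

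Reference genes and chromosome genes were used to check scaling and labels. The median of the common reference genes was -0.06, or 0.058 after quantile normalization, and 18 of the 20 differed by less than 2-fold. Gusb and Actb were 2.39-fold and 2.16-fold higher, while Gapdh had a log2 difference of -0.31 and Hprt of 0.07. The Y-linked genes Ddx3y, Eif2s3y and Uty were detected on both arrays, with log2 differences of -0.51, -0.22 and -0.56 and a list median of -0.51, which was -0.29 with normexp and -0.22 without a filter on dim probes. Xist, which is transcribed from the inactive X chromosome of females, and Kdm5d were not well above background on either array.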

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

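The test for faults of single spots was chosen after Dbp and Ciart, which it counts, had been seen at the end of the ranking, and the test of more atrium as the whole cause after the atrial median had been seen. The rule that a list median must pass its bound by more than its spread, in either direction, was added after first values had been seen. So were the estimates of the spread between probes other than the first. Those came after the first estimate had passed the bound set for excluding a smaller share of cardiomyocyte RNA.

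Among probes outside the comparisons, which the files and the name table pair with no gene, 47 of 3119 measured were at least 4-fold brighter on the infarcted array and 50 were at least 4-fold dimmer. Together that is 3.11% of them, against 2.66% of named probes, so the share differed little.

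Genes of macrophages and monocytes were higher in the infarcted heart, with a median of 1.52 on the log2 scale, and neutrophil and chemokine genes were higher with them. More blood left in the infarcted heart would raise erythroid genes alike, but their median was -0.44 (SD 0.18 over resampled members), which argues against blood of unaltered make-up. Platelet and megakaryocyte genes went the other way, with a median of 0.56 and all 9 measured above 0, so blood of altered make-up was not excluded. Under the scaling alternatives the macrophage median was never below 1.55 (SD 0.19 over resampled members). Those alternatives moved the median of all genes by at most 0.05, so they could hardly have undone a difference of that size. Scaling to spike-in controls, chosen after the data were seen, does not rest on most genes being unchanged. It gave 1.56, which argues against scaling as the cause. More leukocytes in the tissue and higher expression within cells already there may both be at work and were not separated, and the single array per group leaves differences between animals and hybridisations open.

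Genes of the cardiomyocyte, sarcomere and ion channel lists together were lower, with 60 of 63 genes detected on both arrays below 0 and a median of -0.78. With a smaller share of cardiomyocyte RNA as the whole cause, their differences were predicted to spread no more than probes of the same gene do. Their SD was 0.47. The prediction holds only for genes that cardiomyocytes alone express. Listed genes that other heart cells also express would fall by less, so a wide spread cannot exclude the explanation. The first measure of the spread between probes was the median SD between probes of a gene over all genes. The SD of 0.47 was 2.93 times that measure and 2.08 times a robust pooled SD. Both ratios passed the bound of 2 set beforehand for excluding the explanation. A root mean square SD, which like the SD over genes counts large deviations, gave 1.35. The 0.38 found among 27 cardiomyocyte genes with several probes gave 1.24, so the estimates lie on both sides of the bound. The differences of the cardiomyocyte genes also followed signal level, with a Spearman correlation of 0.38 between difference and mean level. With these genes split into 4 groups by level, the medians were -0.96, -0.82, -0.67 and -0.42, from the dimmest group to the brightest. The SD of 0.47 therefore includes a trend with level, whose cause was not tested. A smaller share of cardiomyocyte RNA thus cannot be told apart from changes within cardiomyocytes. More atrium in place of ventricle as the whole cause is argued against by the atrial median of -0.59 (SD 0.14 over resampled members), which it would need above 0; whether the mix also differed stays open, as the atrial median exceeded the ventricular one by 0.24 (SD 0.31).

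Clock output genes were lower in the infarcted heart: 8 of 10 were at least 2-fold lower, with a median of -2.16 (matched range -0.47 to 0.32), and without Dbp and Ciart 6 of 8 were, with a median of -1.78. Faults of single spots are argued against by that number of genes moving together. Collection at a different time of day would move the clock genes of opposite phase the other way. Of these, 4 of 5 were above 0: Arntl was 7.79-fold higher, Npas2 at least 3.07-fold, Nfil3 1.91-fold and Clock 1.52-fold. Cry1, detected in the sham heart alone, was lower. The median of the 5 was 0.93, above its matched range of -0.69 to 0.69, or 0.53 with normexp. It met the bound of 0.5 set for a different hour of collection, but by less than its spread (SD 0.69 over resampled members). By the spread rule, which was added after first values had been seen, a different hour of collection stays open. Without that rule the prediction for a different hour was met. An effect of infarction on the clock also stays open and was not tested, and no collection times are given in the sources used here.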

How the results depend on the processing

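Spike-in scaling was chosen after the data were seen. No median of the fixed lists outside the central range of matched lists, no median of the 3 added lists and no named gene with a called difference changed sign under the 10 alternatives; 8 of the 21 list medians within that range did. Against lists matched within each alternative, which was tried after the data were seen, 24 of the 29 lists outside the range stayed outside it; interferon-stimulated genes, fibroblasts, cardiomyocytes, adipocytes and platelets came within it under at least 1 alternative, and complement, lymphatic endothelium and Schwann cells came to lie outside it. Scaling moved the median of all genes by at most 0.05 and left the split between higher and lower genes within 10 percentage points of the main 58.6%. No paired analysis was possible because each group holds 1 array and no test was run, and leaving out a replicate would leave a group empty. The cause was not tested, except that the filters change which genes enter.

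With normexp, 840 genes were at least 2-fold higher and 582 lower, and 101 and 53 at 4-fold, with 825 of the 1381 higher and 573 of the 974 lower genes kept at 2-fold. Without a filter on dim probes 1702 genes were at least 2-fold lower, 558 at least 4-fold higher and 381 at least 4-fold lower, and among genes detected on both arrays 62 were at least 4-fold lower. Medians with normexp were 0.83 for matrix proteases, 0.76 for chemokines, 0.75 for chemokine receptors, 0.52 for cytokines, 1.78 for cell cycle, -0.29 for chromosome genes, 1.55 for activated fibroblasts, 0.45 for neutrophils, -0.24 for T cells, -0.11 for B cells, -0.16 for NK cells, 0.17 for platelets and -0.21 for lung epithelium. Quantile normalization gave -0.57 for the tricarboxylic acid cycle, -0.39 for oxidative phosphorylation, -0.038 for glycolysis, 0.29 for ribosomal proteins and -0.30 for cardiomyocytes. The authors' processed values gave -0.026 for glycolysis and -0.25 for cardiomyocytes. Without the dim filter the medians were -0.22 for chromosome genes, -0.60 for ventricular markers, -0.62 for lymphatic endothelium, -0.28 for adipocytes and -0.16 for thymocytes. Genes detected on both arrays gave 0.96 for chemokines, -0.045 for complement, -0.60 for ventricular markers, -0.24 for mast cells, 0.33 for lung epithelium and -0.17 for thymocytes. Among the added lists, normexp gave -1.60 for clock output genes, 0.53 for those of opposite phase and -1.38 for the GTPases, and genes detected on both arrays -1.91 for clock output. The mean over probes gave 0.13 for complement and 0.37 for platelets. Of 267 named genes, normexp moved 98, the mean over probes 18, no filter 14, quantile normalization 12 and the authors' values 11; the other alternatives moved 0, although genes detected on both arrays gave values for 244 of them. Signal over background limits the dim genes: 1.11% of undetected repeated spots lay at least 4-fold above their probe's median, against 0.0873% of detected spots off by as much.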

Other observations

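The list of interferon-gamma inducible GTPases and the clock lists were made after some of their genes had been seen.

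Interferon-gamma inducible GTPases, which act against pathogens inside cells, were lower in the infarcted heart as a group. Of 15 measured, 9 were at least 2-fold lower, all 15 were below 0, and the median was -1.55 (matched range -0.40 to 0.24). Without Igtp and Gbp6, which led to the list, 7 of 13 were at least 2-fold lower, with a median of -1.53. Iigp1 was 6.27-fold lower, Irgm2 4.41-fold and Tgtp1, chosen after its value was seen, 3.88-fold. Among the 28 interferon-stimulated genes of the fixed list the median was 0.16, with Mx1 3.36-fold and Oasl1 2.60-fold higher. Of those 28, 16 lay above 0 and 12 below 0, and 1 was at least 2-fold lower. Related members of the GTPase family can share hybridisation. With 1 sample per group it was not tested whether the sham sample stood high or the infarcted sample low.

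Spike-in control RNA was brighter on the infarcted array by 0.28 on the log2 scale over 228 spots of 8 probes before scaling, and differed by -0.04 after scaling.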
